A study of Mus musculus with 52 samples.

How the data were processed

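Chromatin immunoprecipitation with sequencing was measured in primary culture neurons of CD1 mice, with neuronal activity for up to 360 min, in vehicle (DMSO) or in U0126, an inhibitor of the kinases MEK1 and MEK2 that activate ERK. The labels do not name the stimulus. Per the labels' protocols, neurons were fixed in formaldehyde at 1%, chromatin was sonicated and immunoprecipitated with anti-RNA Pol II (abcam ab817) or anti-H3K27ac (abcam ab4729), and libraries were made with a NuGen Ultralow V2 kit. The series holds 52 samples. Of these, 31 are Pol II libraries in 16 groups, 16 are H3K27ac libraries in 8 groups, and 5 are input libraries that have no column in the tables and were not analysed here. Each group of the 2 antibodies has 2 libraries, except Pol II in U0126 at 180 min, which has 1. Nothing in the labels says whether libraries of a group come from separate cultures, so p-values measure only the spread between these samples, which may be technical.

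The processing notes name Bowtie2, SAMtools, bedtools and the mm9 build; versions and settings are not given in the sources used here. For Pol II, the deposited values are a normalized signal per transcription start site (TSS) window, named normalized Pol II density per the file headers, and a set of control TSSs without activity regulation was used by the authors for normalization, per the same headers. The table holds 27815 windows of 600 bp for 24194 gene symbols. The study marked 731 windows as control, 19 as rapid (rPRG) and 116 as delayed (dPRG) activity-regulated TSSs. For H3K27ac, the deposited values are a normalized signal per enhancer region, whose scale is not stated, in 1 sheet per replicate number with the gene named as nearest and its distance. The distance columns are in bp, per the file headers (other unit, not a signal), and were used only to describe regions. No table holds read counts, so the sequencing depth of each library is unknown and no counting interval can be given.

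For each gene symbol, the TSS window with the highest mean over all libraries was used, and the upper 50 percent of genes by mean density (at least 0.301) were tested, which left 12097 genes. All 940 H3K27ac regions were tested. Values were analysed as log2 of the value plus a pseudocount, set at percentile 25 of the positive values (0.148 for Pol II and 0.628 for H3K27ac), and each library was centred on its median. The pseudocount makes the log2 fold changes of genes with low density smaller than their ratio of densities. Groups were compared with limma 3.58.1 in R 4.3.3, with a mean per group, a trend of the variance with mean signal and no other terms. Residual degrees of freedom were 15 for Pol II and 8 for H3K27ac, and 18.7 and 4.17 were added by the moderation. Genes and regions with a Benjamini-Hochberg adjusted p under 0.05 were called. The spread of the single U0126 library at 180 min was assumed to be that of the other groups.

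Activity was compared with unstimulated vehicle libraries of 1 h for 1, 10, 30 and 60 min and of 6 h for 180 and 360 min. The U0126 effect was U0126 minus vehicle at each time, and an interaction was the difference between the activity effects of the 2 arms. These comparisons, 14 gene lists and the rule for named genes were fixed before the data were examined. The rule took, per Pol II comparison, up to 5 genes with the largest rise and up to 5 with the largest fall among those called, any member of the rapid immediate-early list, and up to 4 members of every other list by the size of the log2 fold change. For H3K27ac it took the same numbers of called regions and the regions of the rapid and delayed lists. Predicted genes, microRNAs and similar entries were skipped by the pattern of their names. Where fewer than 3 features were called, the top 3 by unadjusted p could be named. The values of 1 gene taken by the rule are not reported here. Activity within the U0126 arm, the U0126 effect averaged over 10, 30 and 60 min, the study-marked TSS sets, windows of alternative TSSs and differences between times were added after the data were seen.

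The lists were rapid immediate-early, delayed activity-regulated, late and secreted, ERK feedback and ERK targets, SRF actin cytoskeleton, excitatory synapse, GABAergic neuron, astrocyte, oligodendrocyte lineage, microglia, endothelial and fibroblast, cell cycle, stress and heat shock, and ribosomal proteins. No gene is in more than 1 list. For microglia 0 and for endothelial and fibroblast 1 of the 12 genes passed the filter, so these lists were not tested, and adjusted p-values of lists are over the remaining 12 within each comparison. The study marked 16 of the 20 rapid genes tested as rapid and 12 of the 27 delayed genes tested as delayed TSSs, so counts within these lists are not independent evidence of activity regulation. Lists were tested with fry of limma, which asks whether the genes of a list move on balance in 1 direction and compares them with no other genes, and beside it with camera with an estimated correlation. List scores were also compared between drugs with a two-sided exact permutation test of the drug labels within each time, for which 216 arrangements allow no p under 0.00926.

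Replicate numbers are shared by all groups. The differences between the 2 libraries of a group were correlated between groups, across features. For H3K27ac all 28 pairs of groups had a correlation over 0.1 (0.28 to 0.887, median 0.522), and 16 of 16 libraries were closest to libraries with their own number. H3K27ac was therefore also fitted with the replicate number as a block, which is called the blocked fit. For Pol II 10 of the 105 pairs were under 0.1 (range -0.0423 to 0.503, median 0.256), although 30 of 31 libraries were closest to libraries with their own number. Because of the pairs under 0.1 the number was kept out of the comparisons. The block was used only as an alternative, so a structure by number remains in the spread of the main fits.

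The procedure was tested on simulated data. Values were drawn at random around the measured mean of each gene or region, with its moderated SD, and changes were added to 1 group. The simulated libraries had no difference beyond this spread, such as one linked to the replicate number. The rates below therefore hold for simpler data than the measured ones. In a simulated Pol II comparison of 2 against 2 libraries, 46% of genes raised by 1 on the log2 scale and 98% of those raised by 2 were called, with 4 false calls among 141. In the H3K27ac simulation 26.7% and 93.3% of raised regions were called, with 0 false calls among 32. The alternatives fixed in advance were no filter (for H3K27ac, a filter to the upper 50 percent of regions), a pseudocount at percentile 50 (0.338 and 1.01), quantile normalization, the replicate block, the mean of both unstimulated groups as baseline, and leaving out each library in turn. Cyclic loess, the values as deposited without centring, and leaving out both 30 min libraries numbered 1 were chosen after the data were seen.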

Results

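RNA polymerase II (Pol II) and acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active enhancers and promoters, were measured by ChIP-seq in mouse primary neurons during neuronal activity, with and without inhibition of MEK. Pol II was measured at 1, 10, 30, 60, 180 and 360 min and in unstimulated neurons kept for 1 h or 6 h, in both arms. H3K27ac was measured in unstimulated neurons and at 10, 30 and 60 min. Each group had 2 libraries, except Pol II in U0126 at 180 min with 1. The summed Pol II signal of the 31 libraries was between 15570 and 18510, and the median density of the control TSSs was between 0.998 and 1.018. The authors used the control TSSs for normalization, so this narrow range is not an independent check. The share of windows at 0 was between 0.723% and 11.5%, with the highest value in vehicle 30 min replicate 1. Replicates correlated across genes with r between 0.75 and 0.86. Summed H3K27ac signal over the 940 regions was between 1129 and 1624, and replicates correlated across regions with r between 0.302 and 0.798. Genes and regions within a library are not independent replicates.

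The first question was at which TSSs, and how early, Pol II density changed with activity. At 10 min in vehicle, Pol II was higher at the TSSs of immediate-early transcription factors. At Egr1, a zinc finger factor (chromosome 18, 35020560 to 35021160, mm9), density was 1.59 ± 0.0231 (SD, n = 2) in unstimulated neurons and 9.13 ± 2.89 at 10 min, a log2 fold change of 2.37 (SE 0.261, adjusted p 9.17e-07). Fos, a component of the AP-1 factor (chromosome 12, 86814550 to 86815150), went from 2.15 ± 0.214 to 7.31 ± 0.299, a log2 fold change of 1.68 (SE 0.23, adjusted p 5.51e-05). Egr3 rose by 2.26 (SE 0.426), the AP-1 members Fosb and Maff by 1.86 and 1.62, the nuclear receptor Nr4a1 by 1.56 and Npas4, a factor of inhibitory synapse formation, by 1.11. The single called fall was at Wdr83os, -1.61 (SE 0.358, adjusted p 0.0462), and it was lost without any 1 of the 4 libraries. The calls of Egr1 and Fos at 10 min were kept under every alternative run and without each library in turn.

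At 10 min 22 genes were higher and 1 was lower, and 1161 had an unadjusted p under 0.05. The rapid immediate-early list rose with a median of 0.78 (fry adjusted p 7.16e-05). Of its 20 genes 19 had a positive log2 fold change, 7 were called, and 14 passed when adjusted over the list alone. Junb (0.86), Dusp1 (0.95) and Arc (0.66) did not pass over all genes. The delayed list rose with a median of 0.55 (adjusted p 0.00425), with 2 of 27 genes called, Nr4a3 (1.53) and the synaptic scaffold gene Homer1 (1.58), and 10 when adjusted over the list alone. The ERK feedback list rose with a median of 0.46 (adjusted p 0.00291), 0 of 23 called and 3 adjusted over the list alone, with the phosphatase gene Dusp6 at 1.07 and the ERK pathway inhibitor Spry4 at 1.00. The SRF actin list rose by 0.23 (adjusted p 0.0101, 2 of 12 called and 2 adjusted over the list alone), and the ribosomal protein list by 0.51 (adjusted p 7.16e-05). All 30 ribosomal genes had a positive value, among them Rpl23 (0.85) and Rps7 (0.84), but 0 were called by limma over all genes and 8 when adjusted over the list alone. The late and secreted list did not pass (0.10, adjusted p 0.255). Against lists of as many genes matched for density, with a median of 0.245 over 10000 drawn lists, the ribosomal median was at percentile 100. It was 0.294 with quantile normalization and 0.271 with cyclic loess, still called, and without the filter (0.555, adjusted p 0.126) the call was lost. The count of calls was 4 without vehicle 10 min replicate 1, and 6 and 14 without vehicle unstimulated 1 h replicates 1 and 2. It was 7 with quantile normalization and 5 without the filter.

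At 30 min the nuclear receptor genes of the Nr4a family were among the largest changes. Nr4a2, a factor also required by dopamine neurons (chromosome 2, 56967149 to 56967749), had a density of 0.542 ± 0.302 (SD, n = 2) before and 3.47 ± 1.38 at 30 min, a log2 fold change of 2.38 (SE 0.318, adjusted p 1.91e-05). Nr4a3 rose by 2.33, Nr4a1 by 2.24 and Maff by 2.11. Among genes the rule could name the largest value was at Ovca2 (chromosome 11, 74992010 to 74992610), 2.48 (SE 0.299, adjusted p 5.06e-06). The windows of the microRNA genes Mir132 (74986883 to 74987483) and Mir212 (74986589 to 74987189), which the rule skipped, are close to that of Ovca2. Fos was at 9.38 ± 2.90 (log2 fold change 1.99, adjusted p 2.56e-06), and Egr1 at 6.50 ± 2.30 (1.87, adjusted p 4.74e-05), below its 10 min mean but within the spread of the libraries. The 22 called falls included Gm3500 (-1.68, adjusted p 0.0299), a predicted gene that the rule skipped. Among those the rule could name the largest were at Kcnv1, a modifier subunit of potassium channels, -1.59 (SE 0.384, adjusted p 0.0308), Fbxl17 (-1.52), Ntsr1, a neurotensin receptor (-1.51), Pitpnm2 (-1.51) and Dynlrb2 (-1.51). The calls of Ovca2, Nr4a1, Nr4a2, Nr4a3, Maff, Fos and Egr1 at 30 min were kept under every alternative run and without each library in turn.

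At 30 min 150 genes were higher and 22 lower, and 1778 had an unadjusted p under 0.05. The rapid list rose with a median of 1.30 (adjusted p 1.06e-05), with 10 of 20 called and 16 adjusted over the list alone. Npas4 rose by 1.48, the MAP kinase phosphatase gene Dusp1 by 1.51, Junb by 1.32 and Cyr61, which encodes a secreted matrix protein, by 1.37. Egr3 (1.43), Egr4 (1.28) and Arc (0.51) did not pass, and Zfp36 stayed near 0. Of the delayed list (0.76, adjusted p 2.95e-04), 6 of 27 were called and 18 adjusted over the list alone, among them Sik1 (1.49) and Gadd45b (1.36). In the ERK feedback list (0.44, adjusted p 3.22e-04), Fosl2 (1.80), Dusp5 (1.65) and Spry4 (1.31) were called, and 4 passed when adjusted over the list alone. In the late list (0.37, adjusted p 0.00442; 0.0505 with an estimated correlation) 2 of 12 were called, Pcsk1 (1.78), a convertase of neuropeptide precursors, and Vgf (1.49), a neuropeptide precursor, and 3 adjusted over the list alone. The ribosomal list rose by 0.58 (adjusted p 1.33e-05), 2 of 30 called, among them Rps2 (0.87), and 20 adjusted over the list alone. The list median was 0.294 with quantile normalization and 0.312 with cyclic loess, still called. Rps2 was not called with quantile normalization, and density-matched lists had a median of 0.332. The stress and heat shock list rose by 0.56 (adjusted p 0.0236; 0.118 with an estimated correlation), with 1 of 14 called and 5 adjusted over the list alone.

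The excitatory synapse list was lower at 30 min with a median of -0.22 (adjusted p 0.0299; 0.161 with an estimated correlation), with 12 of 17 genes lower. Its called gene was Grin1, an NMDA receptor subunit, which was higher (0.97), while Camk4 (-1.20, adjusted p 0.101) did not pass. Adjusted over the list alone 1 gene was higher and 2 were lower. At 30 min the lists for GABAergic neurons (0.04, adjusted p 0.638), astrocytes (0.35, 0.0743), the oligodendrocyte lineage (-0.03, 0.638) and the cell cycle (0.16, 0.348) did not pass. The SRF actin list did not pass either (adjusted p 0.125), and its median of -0.04 and mean of 0.15 differed in sign, with fry pointing up. The number of calls at 30 min rested on single libraries. It was 10 without vehicle 30 min replicate 1, 578 without replicate 2 of that group, and 9 and 110 without vehicle unstimulated 1 h replicates 1 and 2. With quantile normalization it was 15, of which 1 was lower.

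**Figure D1:**
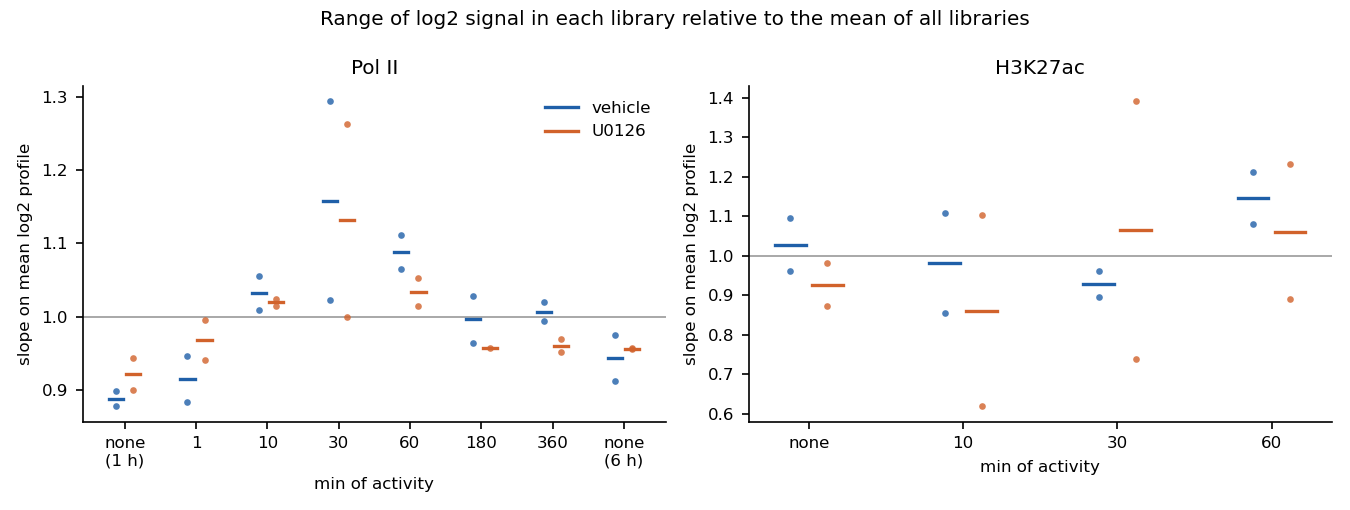
Slope of each library's log2 signal on the mean of all libraries (vertical axis, no unit; the line marks 1) by min of activity (horizontal axis) for Pol II (left) and H3K27ac (right); dots are libraries, bars are group means, blue is vehicle and orange is U0126. Vehicle 30 min replicate 1 has the highest Pol II slope, 1.29.

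At 60 min Pol II stayed high at the Nr4a genes. Nr4a2 was 2.10 above unstimulated neurons on the log2 scale (SE 0.318, adjusted p 3.56e-04, n = 2 per group), Ovca2 2.09, Nr4a1 2.02 and Nr4a3 2.00, and Mmp23, a matrix metalloproteinase gene, rose by 1.80. Egr1 (1.54), Npas4 (1.42) and Fos (1.42) were still called, while Egr3 (0.62) and Fosb (1.57) did not pass. In all 19 genes were higher and 0 lower by limma, with 1290 at an unadjusted p under 0.05. The rapid list had a median of 0.90 (adjusted p 2.95e-04, 7 of 20 called, 13 adjusted over the list alone), the delayed list 0.52 (adjusted p 0.00171, 2 of 27, 10 adjusted over the list alone) and the ERK feedback list 0.60 (adjusted p 2.95e-04, 0 of 23, 4 adjusted over the list alone). The ribosomal list rose by 0.35 (adjusted p 0.00171, 0 of 30, 0 adjusted over the list alone), and the late list by 0.31 (adjusted p 0.0164; 0.0831 with an estimated correlation), with Pcsk1 (1.74) called and 2 adjusted over the list alone. With quantile normalization the ribosomal median was 0.109 and did not pass, and density-matched lists had a median of 0.249. The count of calls was 3 without vehicle unstimulated 1 h replicate 1, and 7 and 10 without vehicle 60 min replicates 1 and 2.

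**Figure D2:**
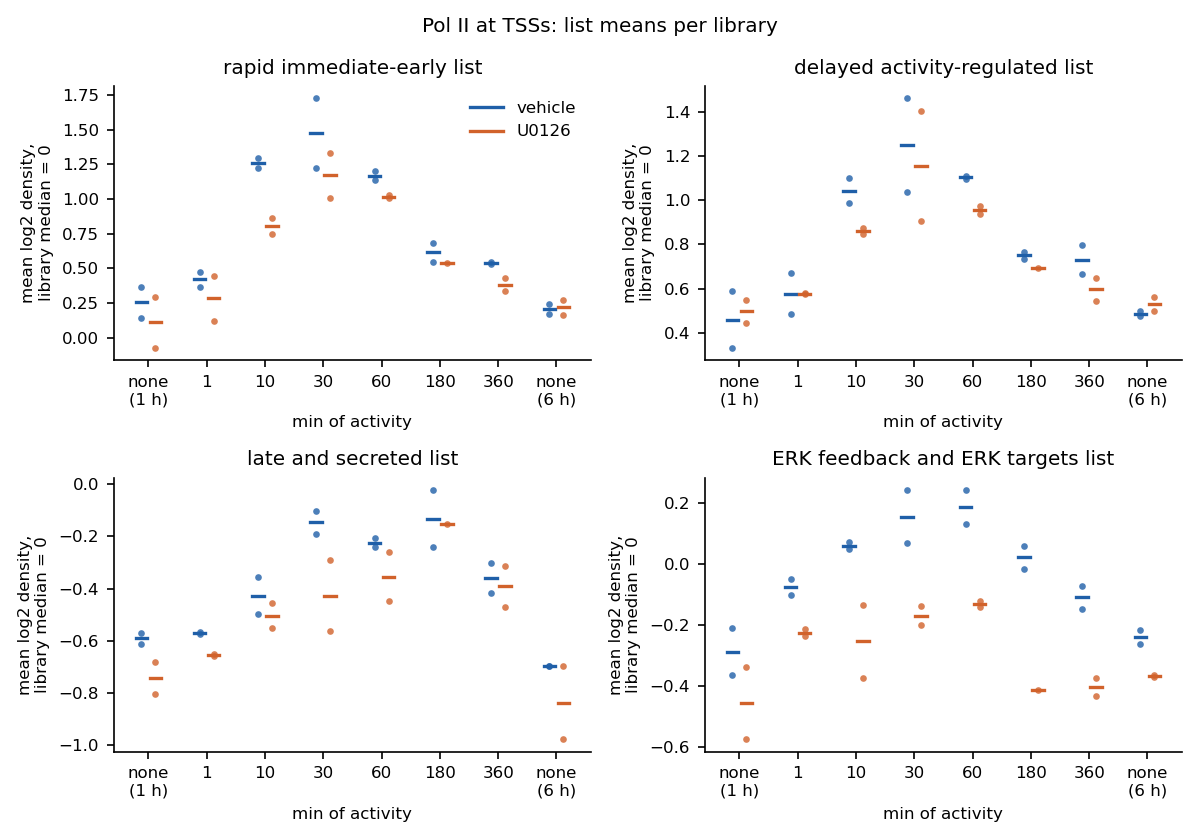
Mean log2 Pol II density over the genes of 4 lists (vertical axis, library median at 0) by min of activity (horizontal axis); dots are libraries, bars are group means, blue is vehicle and orange is U0126. In vehicle the median log2 fold change of the rapid list was 0.78 at 10 min, 1.30 at 30 min and 0.90 at 60 min.

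At 1 min no gene passed, but Egr1 had the lowest p, with a log2 fold change of 1.10 (SE 0.261, n = 2 per group, adjusted p 0.801). limma called 0 genes, with 415 at an unadjusted p under 0.05, and the rapid list had a median of 0.17 (adjusted p 0.575). At 180 min, against unstimulated libraries of 6 h, the late and secreted list rose with a median of 0.56 (adjusted p 9.59e-04; 0.00192 with an estimated correlation). Without the filter the median was 0.335 and did not pass (adjusted p 0.148). Of the 25 genes of the list 12 passed the filter. All 12 had a positive value, among them Pcsk1 (1.11), the receptor gene Gpr3 (0.88), the granin Scg2 (0.84) and Nptx2, which clusters AMPA receptors (0.69). None was called over all genes or adjusted over the list alone. The rapid list was at 0.42 (adjusted p 0.0506) and the delayed list at 0.19 (adjusted p 0.202), and the rapid (0.30) and late (0.39) lists did not pass at 360 min. limma called 0 genes at 180 min (592 at an unadjusted p under 0.05; Rdm1 had the lowest adjusted p, 0.112) and 0 at 360 min (375). Between unstimulated vehicle neurons of 6 h and 1 h no gene passed (0 called by limma, 342 at an unadjusted p under 0.05).

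**Figure D3:**
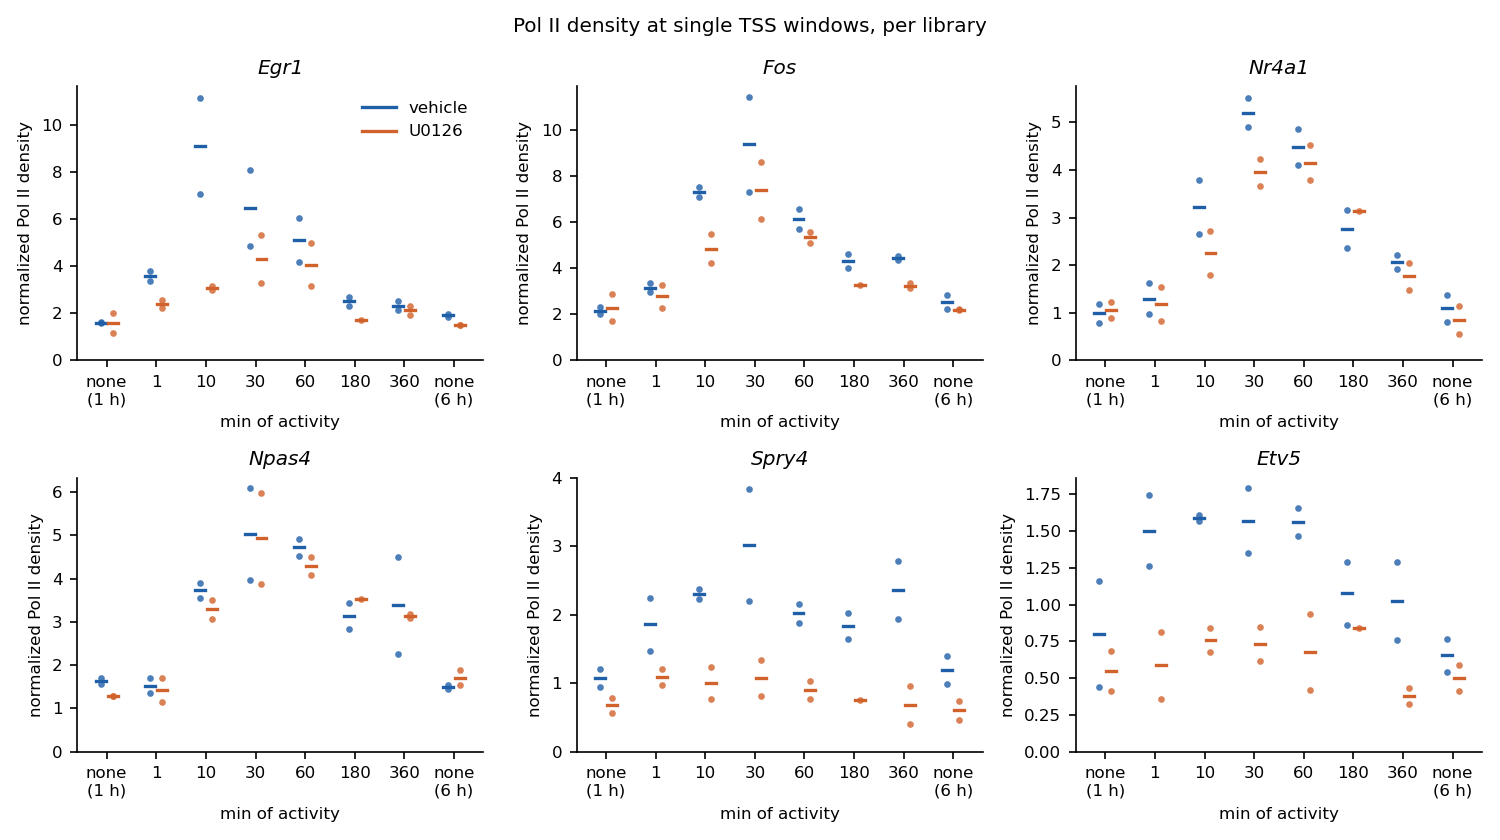
Normalized Pol II density in the TSS windows of Egr1, Fos, Nr4a1, Npas4, Spry4 and Etv5 (vertical axis) by min of activity (horizontal axis); dots are libraries, bars are group means, blue is vehicle and orange is U0126. At 10 min Egr1 had a mean of 9.13 in vehicle and 3.06 in U0126, and at 360 min Spry4 had 2.36 and 0.678.

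Over the 19 TSSs that the study had marked as rapid the median log2 fold change in vehicle was 0.82 at 10 min, 1.32 at 30 min and 1.01 at 60 min. Over its 116 delayed TSSs it was 0.29, 0.29 and 0.35, and over 656 control TSSs 0.02, 0.01 and 0.01. All rapid and delayed windows were used, of which 18 and 72 were among the windows tested, but only control windows that were tested. The pseudocount makes changes at low density smaller, so the sets are not strictly comparable. The control TSSs served the authors for normalization, so their values near 0 are not an independent result. Since the study marked the rapid and delayed TSSs as activity-regulated, and it is not stated from which samples, their values are not independent evidence either. The same holds for regions nearest to these genes. Of the 150 genes higher at 30 min, 10 were marked rapid, 8 delayed, 2 control and 130 other.

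The second question was what MEK inhibition changed. Egr1 was the gene with a called U0126 effect at a single time. At 10 min its density was 3.06 ± 0.115 (SD, n = 2) in U0126 against 9.13 ± 2.89 in vehicle, a log2 difference of -1.49 (SE 0.261, adjusted p 0.0274). In unstimulated neurons of 1 h it was 1.59 ± 0.626 in U0126, and the log2 difference there was -0.04. The difference was -0.56 at 30 min and -0.35 at 60 min and did not pass at either. The interaction at 10 min was -1.44 (SE 0.37, unadjusted p 4.34e-04) and did not pass over all genes (adjusted p 1), so the rise of Egr1 was not shown to differ between the arms. The Egr1 call was lost without a filter (-1.44, adjusted p 0.587), with quantile normalization (-1.23, 0.0806), and without vehicle replicate 1 (-1.15, 0.998), U0126 replicate 1 (-1.52, 0.626) or U0126 replicate 2 (-1.45, 0.378) of 10 min. Of the other rapid genes at 10 min, Egr3 was at -1.32 and Egr2 at -1.24, while Fos was at -0.58, Fosb at -0.45, Nr4a1 at -0.48 and Npas4 at -0.16, and none of these passed.

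Spry4, whose product inhibits the ERK pathway, was lower in U0126 at all 8 times and conditions (chromosome 18, 38760622 to 38761222). The log2 difference was -1.11 at 10 min, -1.35 at 30 min, -1.08 at 60 min and -1.69 at 360 min (SE 0.319, adjusted p 0.0859), where density was 2.36 ± 0.594 (SD, n = 2) in vehicle and 0.678 ± 0.395 in U0126. In unstimulated neurons it was -0.57 (1 h) and -0.83 (6 h), and it passed at no single time. Averaged over 10, 30 and 60 min, Spry4 fell by 1.18 (SE 0.184, adjusted p 0.00328) and Egr1 by 0.80 (SE 0.151, adjusted p 0.0443). These were the 2 genes called, and 359 had an unadjusted p under 0.05. Etv5, an ETS factor induced by ERK signalling, was at -1.01 (SE 0.21, adjusted p 0.119). The call of Spry4 was lost without U0126 10 min replicate 1 (-1.08, adjusted p 0.0548) or vehicle 30 min replicate 1 (-1.05, 0.0631), and the count was then 0. That of Egr1 was lost without 7 of the 12 libraries, at values between -0.81 and -0.68. It was also lost without the filter (-0.828, adjusted p 0.393), with quantile normalization (-0.644, 0.122) and with values as deposited (-0.798, 0.0625). With the replicate block both calls were kept (limma adjusted p 1.13e-04 for Egr1 and 6.91e-07 for Spry4). Spry4 was also kept under the other alternatives with all libraries.

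The ERK feedback list was lower in U0126, with a median of -0.23 in the average of 10, 30 and 60 min (fry adjusted p 1.46e-04; 6.68e-05 with an estimated correlation). Of its 23 genes 21 were lower, 1 was called over all genes and 4 adjusted over the list alone. Spred1 (-0.65) and Dusp6 (-0.59) were lower without a call. At the single times the medians were -0.24 at 10 min (adjusted p 0.0418), -0.30 at 30 min (0.0335) and -0.30 at 60 min (0.0221), and the list did not pass in unstimulated neurons (-0.20 at 1 h, -0.07 at 6 h), at 1 min (-0.23) or at 360 min (-0.22, adjusted p 0.0533). The calls at 10, 30 and 60 min were each lost without 3 of the 4 libraries. With 1 library left out the medians were -0.345 to -0.261 at 10 min, -0.373 to -0.17 at 30 min and -0.432 to -0.0707 at 60 min, nearest to 0 at 30 and 60 min without vehicle replicate 1 of that time. The average stayed called without any 1 of its 12 libraries, but not without the filter (-0.257, adjusted p 0.103). Without the filter the calls at 10, 30 and 60 min were lost too, at medians of -0.195, -0.294 and -0.435. Those at 10 and 30 min were also lost with quantile normalization (-0.22 and -0.239) and with cyclic loess (-0.236 and -0.309). At 180 min the median was -0.40, but U0126 had 1 library there, so its spread was borrowed from the other groups and the value is not counted as a call. The mean score of the list differed by -0.32 between drugs and was lower in 6 of 6 pairs of libraries that share time and number, with a two-sided exact permutation p of 0.00926. This is the smallest p the design allows, and it was 0.111 after adjustment over 16 relations. The rapid, delayed, late and ribosomal lists were also lower in 6 of 6 pairs, with differences of -0.30, -0.14, -0.16 and -0.10 and exact permutation p-values of 0.0278, 0.194, 0.0278 and 0.0741. The oligodendrocyte lineage list differed by -0.21 and was lower in 5 of 6 pairs (exact permutation p 0.0463, adjusted 0.123). No list passed this test after adjustment. A single list at the smallest p could not have passed over 16 relations, so for the ERK feedback list the adjusted value decides nothing.

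The rapid list was lower in the average, with a median of -0.28 (adjusted p 0.039; 0.0194 with an estimated correlation; 19 of 20 lower, 1 called, 5 adjusted over the list alone), with Egr3 at -0.87, Egr2 at -0.77, Arc at -0.47, Fos at -0.37 and Npas4 at -0.11. It did not pass at 10 min (-0.36, adjusted p 0.0977), 30 min (-0.28) or 60 min (-0.15), its exact permutation p was 0.0278 (adjusted 0.111), and its call in the average was lost without 8 of the 12 libraries, with the value nearest to 0, -0.159, without vehicle 30 min replicate 1. The call was also lost without the filter (-0.305, adjusted p 0.263) and with quantile normalization (-0.189, 0.051). The delayed list was at -0.12 (adjusted p 0.258) and the late list at -0.17 (adjusted p 0.0792). The study-marked rapid TSSs were at -0.30 (fry adjusted p 0.0293, 17 of 19 lower) and its delayed TSSs at -0.04. The difference between these sets had an exact permutation p of 0.037 (adjusted 0.119), so the sets were not shown to differ. Between the ERK feedback and rapid lists the exact permutation p was 0.824. The interaction of the rapid list was -0.25, -0.19 and -0.06 at 10, 30 and 60 min (adjusted p 0.837, 0.756 and 0.964), that of the ERK feedback list -0.21, -0.02 and -0.06 with the same adjusted p-values, and that of the delayed list at 60 min -0.11 (0.964). limma called 0 genes for the interaction at 10, 30, 60 and 360 min, with 339, 232, 288 and 158 at an unadjusted p under 0.05. It called 0 genes for U0126 in unstimulated neurons of 1 h (288) and 6 h (265), and at 1 min (269), 30 min (259), 60 min (302), 180 min (304, with 1 library in U0126) and 360 min (114).

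Immediate-early genes still gained Pol II with MEK inhibited. At 30 min in U0126 Fos rose by 1.64 (adjusted p 9.92e-05) to a density of 7.39 ± 1.76 (SD, n = 2), Npas4 by 1.77 to 4.93 ± 1.47 against 5.02 ± 1.51 in vehicle, Nr4a3 by 2.33, Fosb by 2.31 and Egr1 by 1.35. The rapid list rose by a median of 0.57 at 10 min (adjusted p 0.00267), 1.06 at 30 min (5.86e-05) and 0.99 at 60 min (3.19e-04), with 0, 9 and 5 of 20 genes called and 11, 15 and 15 adjusted over the list alone. The ERK feedback list rose by 0.29 at 30 min (adjusted p 0.00804) and 0.22 at 60 min (0.0116), but did not pass at 10 min (0.25, adjusted p 0.0658). Spry4 (0.53 at 30 min, adjusted p 0.584) did not pass either. In this arm 2, 53 and 14 genes were called at 10, 30 and 60 min, 4 of them lower, all at 30 min. The windows of the 2 genes called at 10 min overlap, so these calls share signal. At 30 min the count was 4 without U0126 30 min replicate 1, 258 without replicate 2, and 5 and 21 without U0126 unstimulated 1 h replicates 1 and 2. At 60 min it was 4 without U0126 60 min replicate 1 or U0126 unstimulated 1 h replicate 1, and 8 without replicate 2 of the latter. Without the filter 0, 12 and 2 genes were called at 10, 30 and 60 min. At 30 min the count was 14 with quantile normalization and 17 with cyclic loess, and at 60 min 10 and 8.

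The third question was whether H3K27ac at enhancer regions changed with activity or with U0126. At 60 min in vehicle the lowest p-values were at regions far from the genes named as nearest. A region 37630 bp from Fos (chromosome 12, 86776490 to 86777950) had a signal of 1.13 ± 0.509 (SD, n = 2) in unstimulated neurons and 3.80 ± 0.295 at 60 min, a log2 fold change of 1.40 (SE 0.289, adjusted p 0.289; blocked fit SE 0.227, adjusted p 0.0189). Regions nearest to Adm, which encodes the peptide adrenomedullin (55108 bp, chromosome 7, 117825760 to 117826820), and to Grasp, a scaffold of glutamate receptors (19608 bp, chromosome 15, 101073710 to 101074780), were higher by 1.18 and 1.33 (blocked adjusted p 0.0295 and 0.0297). The TSS window of Nr4a1 (chromosome 15, 101096976 to 101097576) is also close to the Grasp region. Which gene a region acts on was not tested. A region 85324 bp from Hsd17b12 (chromosome 2, 94082410 to 94084370) went from 1.501 ± 0.653 to 5.07 ± 0.432, a log2 fold change of 1.49 (blocked adjusted p 0.0297).

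limma called 0 of 940 regions for activity at 10, 30 and 60 min in vehicle, with 12, 40 and 37 at an unadjusted p under 0.05. With the blocked fit 7 regions were higher at 60 min and 0 lower. The others were nearest to Fos (39055 bp, 1.07), Fbxo33 (88281 bp, 1.34) and AK140370 (113464 bp, 1.03). This further Fos region (chromosome 12, 86775280 to 86776310) lies beside the one 37630 bp from Fos. The AK140370 region (chromosome 2, 94110960 to 94112100) is named Hsd17b12 in the replicate 2 sheet. The 7 regions may thus not be separate loci. At 10 and 30 min the blocked fit of limma called 0 regions (50 and 140 at an unadjusted p under 0.05), and the region 37630 bp from Fos was at 1.26 (blocked adjusted p 0.059) and 1.15 (0.145). The 90 regions nearest to rapid list genes had a median of 0.17 at 60 min (fry adjusted p 0.606) and the 73 nearest to delayed list genes 0.03 (0.606). The 411 regions nearest to the study's delayed genes rose by 0.12 (fry adjusted p 0.00846; 0.173 with an estimated correlation), with 258 regions higher and 153 lower. This call was lost with cyclic loess and with values as deposited.

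In U0126 at 60 min the blocked fit called 11 regions higher and 1 lower, against 0 by limma without the block (41 at an unadjusted p under 0.05). A region 1024 bp from Npas4 (chromosome 19, 4990470 to 4991520) went from 0.85 ± 0.175 (SD, n = 2) to 3.47 ± 0.804 in U0126, a log2 fold change of 1.47 (blocked adjusted p 0.0289), and from 1.43 ± 0.0299 to 3.96 ± 0.545 in vehicle. The region 37630 bp from Fos rose by 1.29 (blocked adjusted p 0.0289), and the called fall was 38558 bp from Nrn1, which encodes neuritin (-0.83, blocked adjusted p 0.0436). For U0126 against vehicle limma called 0 regions in unstimulated neurons and at 10, 30 and 60 min, with and without the block. Without it 4, 4, 8 and 4 regions had an unadjusted p under 0.05, and with it 16, 16, 19 and 7. The lowest p at 30 min was 97712 bp from Btg2 (-1.05, SE 0.268, adjusted p 1). The interaction had 0 calls at 10, 30 and 60 min (2, 9 and 1 at an unadjusted p under 0.05). The score of the 90 rapid list regions differed between drugs by -0.05 (exact permutation p 0.667), and that of the 73 delayed list regions by 0.00361 (p 0.981). In the simulation, which was of activity at 60 min in vehicle and fitted without the block, 20% of regions lowered by 1 on the log2 scale were called. Without the block a decrease of this size in U0126 would thus mostly not have been detected. The blocked fit was not simulated.

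**Figure D4:**
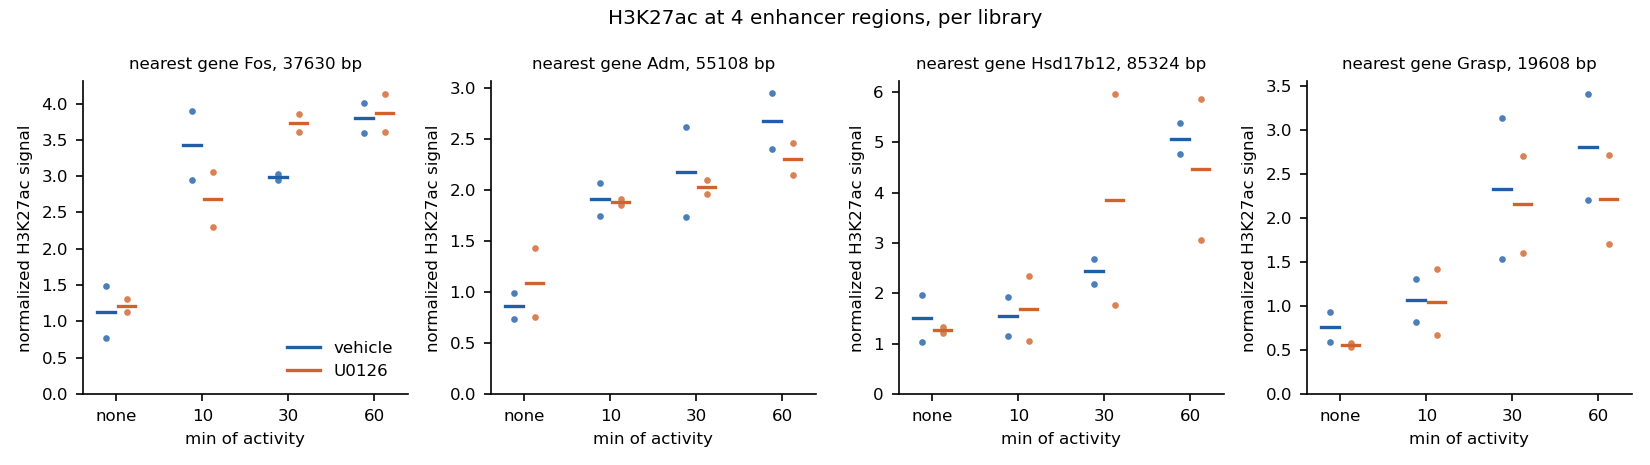
Normalized H3K27ac signal (vertical axis) of 4 regions, nearest to Fos, Adm, Hsd17b12 and Grasp, by min of activity (horizontal axis); dots are libraries, bars are group means, blue is vehicle and orange is U0126. The region 37630 bp from Fos went from a mean of 1.13 to 3.80 in vehicle and from 1.22 to 3.87 in U0126 at 60 min.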

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

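The comparisons between times with their alternatives and matched lists, the windows of further TSSs and the tests of signal range for the 30 min calls, the rapid list at 30 min and the ribosomal list were chosen only after those results were seen; the tests of signal range and of other splits for U0126 were set beforehand. In the test of the 30 min calls the counts compared were changed, after its value was known, from fits with all libraries to fits without replicate 1 of each time.

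Pol II changes of 3 lists differed between times in vehicle, by a fry test of the difference itself over 36 tests. The ribosomal protein list changed less at 180 min than at 10 min, by a median of -0.45 (adjusted p 0.0204), and less than at 30 min, by -0.546 (adjusted p 0.0202). The rapid immediate-early list differed by -0.86 between its changes at 180 and 30 min (adjusted p 0.0204), and the excitatory synapse list by 0.337 (adjusted p 0.0204). The 180 min libraries have unstimulated libraries of 6 h as baseline and the earlier ones those of 1 h; with the mean of both as the baseline all 4 differences passed (-0.345 and -0.426 for the ribosomal list, -0.91 and 0.369 for the others). Density-matched lists moved as well, by -0.157 and -0.248 for the ribosomal list and -0.242 for the rapid list, so part of these differences is shared with other TSSs of that density, while for the excitatory synapse list they were at 0.0529. None of the 4 passed without the filter (-0.471, -0.843, -1.16 and 0.0799) or with quantile normalization (-0.268, -0.276, -0.457 and 0.301), nor did the ribosomal difference from 30 min with cyclic loess (-0.278). With 1 of 8 libraries left out the ribosomal differences did not pass in 4 fits each (-0.591 to -0.284 and -0.676 to -0.369), the rapid one in 5 (-1.09 to -0.496) and the excitatory synapse one in 6 (0.212 to 0.668).

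Among 1442 windows of TSSs that were not the strongest of their gene, and so stand outside the comparisons of genes, several that do not overlap the window used changed with activity. At Rnf138 a window (chromosome 18, 21159500 to 21160100) was higher by 1.40 at 10 min (SE 0.289, adjusted p 0.0115) and 1.25 at 30 min (adjusted p 0.0219), while the window used was at 0.00601 at 10 min. At 30 min such windows were higher at the clock gene Per1 (1.47, adjusted p 0.0335), Cbarp (1.34, 0.0294), Slc25a22 (1.32, 0.032) and Midn (1.13, 0.00344), and lower at Sorbs2 (-1.39). The windows used moved the same way without passing at Per1 (1.07, adjusted p 0.0787), Cbarp (0.444), Midn (0.572) and Sorbs2 (-0.678), and the other way at Slc25a22 (-0.726, adjusted p 0.266). No test compared the 2 windows of a gene, so none of these genes was shown to differ between its TSSs.

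More TSSs were called at 30 min than at 10 or 60 min. A wider signal range of the vehicle replicate 1 library of 30 min, with a slope of 1.29 on the mean profile of all libraries against 1.02 for replicate 2, is a candidate explanation. Without this library 10 TSSs were called, against 4 at 10 min and 7 at 60 min without their own vehicle replicate 1, and 9 at 30 min without vehicle unstimulated 1 h replicate 1, so leaving it out neither supports nor excludes the explanation. For the rise of the rapid list the tables argue against the range of this library, since the median without both replicate 1 libraries of 30 min was 1.1. Other differences in range stay in that fit. The baseline, vehicle unstimulated 1 h, had the lowest mean slope of the Pol II groups, 0.888, against 1.03, 1.16 and 1.09 in vehicle at 10, 30 and 60 min. The rapid median at 30 min was at least 0.969 under every alternative run, among them quantile normalization and cyclic loess. For the number of calls, quantile normalization and cyclic loess make the signal range of libraries more alike. They gave 15 and 21 calls at 30 min, against 172 in the main fit, and 7 and 8 at 10 min. At 60 min no alternative with all libraries gave fewer than 15, against 19. Most of the excess at 30 min was thus lost, as a difference in signal range would give. A larger response of more genes at 30 min, which the design could also give, was not separated from it, since such scaling can remove both.

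The ribosomal protein list, with a high Pol II density, rose at 10, 30 and 60 min. A difference in signal range that lifts strongly bound TSSs in general could give such a rise, and density-matched lists rose too, with medians of 0.245, 0.332 and 0.249. At 10 and 30 min the ribosomal medians were 0.506 and 0.575, at percentile 99.9 or above among 10000 such lists, which argues against this as the whole cause. The lists were drawn gene by gene, so their range leaves out correlation within the ribosomal list, and the percentiles are not a test. At 60 min the ribosomal list lay at percentile 97, inside the central range of these lists, and the explanation stays open. Whether activity acts on these genes was not tested otherwise.

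The ERK feedback and rapid lists had lower Pol II density with U0126 averaged over 10, 30 and 60 min. A difference in signal range between the U0126 and vehicle libraries would lower density-matched lists as well. The ERK feedback median (-0.227) lay at percentile 0 of 10000 such lists (their median -0.0178) and the rapid median (-0.275) also at percentile 0 (-0.0561). By size, density-matched genes thus show only part of these falls, which argues against signal range as the whole cause. The lists were drawn gene by gene, so their range leaves out correlation within a list, and the percentiles are not a test. By the same draw the delayed list, which was not called, was at percentile 0.18. An effect of MEK inhibition on these genes remains a hypothesis, since it was tested on the same libraries and an unlabelled batch was not excluded. Over 100 splits drawn from the 108 possible ones of the 12 libraries within time, chance could not be excluded for the 2 TSSs called, since 15 of these called as many and the highest other called 968.

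That highest split follows the replicate number and points to a structure of the samples other than drug; with the number as a block the real split called 4. The count over the drawn splits therefore mixes this structure with chance. Among the 28 other drawn splits with 1 library of each number per side and time, as in the real split, 0 called any TSS, but the numbers did not meet the limit set for pairing Pol II libraries. For H3K27ac the real split called 0 regions, so 100 of 100 splits called as many by construction and their count says nothing about chance. The highest other count was 471, again from the split by replicate number.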

How the results depend on the processing

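Cyclic loess, values as deposited, the fit without both 30 min libraries numbered 1, and all alternatives for activity within U0126, for the average U0126 effect, for the ERK feedback, late and ribosomal lists and for the H3K27ac region sets were chosen after the data were seen. Unless a reason is given, the cause was not tested. The rise of the rapid list stayed past its threshold under every alternative run, with medians from 0.647 to 0.872 at 10 min, 0.969 to 1.62 at 30 min and 0.797 to 1.18 at 60 min, and so did that of the delayed list at 60 min (0.391 to 0.741). It also did without each single library, from 0.715 to 1.03, 0.933 to 1.55 and 0.914 to 1.25 for the rapid list and from 0.333 to 0.697 for the delayed list. The interactions of genes and the U0126 effects in unstimulated neurons and at 1, 60 and 180 min stayed at 0 calls. Of 87 results of named genes 12 were kept by every alternative. Of their 1022 alternative values 658 passed, 364 did not and 0 reversed. Count-based tests were not run, since the files hold no counts. The unknown depth limits what can be said of genes with low density.

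With the replicate block, Pol II calls for activity in vehicle were 1, 131, 662, 130, 4 and 2 at 1, 10, 30, 60, 180 and 360 min, and 25, 326 and 65 in U0126 at 10, 30 and 60 min. U0126 effects had 2 calls at 10 min, 1 at 30 min and 1 at 360 min, and 4 in the average. For Pol II 30 of 31 libraries were closest to libraries with their own number, but 10 of 105 pairs of groups were under the limit for pairing, so this is a hint from the data and not the design. The block called 7 H3K27ac regions at 60 min in vehicle and 12 in U0126, and changed no other H3K27ac call.

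Without the filter, which adds genes of low density to the test, calls were 5 for activity at 10 min, 0 for U0126 at 10 min, 0, 12 and 2 for activity in U0126 at 10, 30 and 60 min and 1 for the average U0126 effect. Lists then not past the threshold were the rapid list in the average (-0.305), the ERK feedback list at 10 min (-0.195), 30 min (-0.294), 60 min (-0.435), 180 min (-0.586) and in the average (-0.257), the late list at 180 min (0.335) and the ribosomal list at 10 min (0.555). Of 18 calls over all other lists 11 were left.

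Quantile normalization gave 7 and 15 calls at 10 and 30 min, 0 for U0126 at 10 min, 1 for U0126 at 360 min, 14 for activity in U0126 at 30 min, 1 for the average U0126 effect and 1 H3K27ac region in U0126 at 60 min. It made the interaction of the rapid list at 60 min positive (0.0218), and the median of the H3K27ac regions of the delayed list negative (-0.0132). The rapid list in the average (-0.189), the ERK feedback list at 10 min (-0.22) and 30 min (-0.239) and the ribosomal list at 60 min (0.109) no longer passed, while the ERK feedback list at 360 min did (-0.257). With cyclic loess the counts were 8 and 21 at 10 and 30 min, 17 and 8 in U0126 at 30 and 60 min, and 1 H3K27ac region in U0126 at 60 min. The ERK feedback list at 10 min (-0.236) and 30 min (-0.309), the ribosomal list at 60 min (0.0733) and the H3K27ac regions of the study's delayed genes (0.0342) then did not pass, and the regions of the delayed list were at -0.000535. Values as deposited, which differ from the centred ones by a shift per library (-0.0591 to 0.0694 for Pol II, -0.0728 to 0.105 for H3K27ac), gave 1 call in the average, -0.00241 for the regions of the delayed list and 0.0819, not past the threshold, for those of the study's delayed genes.

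With the pseudocount at the median of positive values the ERK feedback list at 360 min passed (-0.188). With the mean of the 1 h and 6 h unstimulated groups as the baseline, which has more libraries, calls were 73, 393, 51 and 1 at 10, 30, 60 and 360 min in vehicle, and 19 and 130 in U0126 at 10 and 30 min. Without both 30 min libraries numbered 1, which leaves 1 library per group, calls were 9 at 30 min in vehicle, 4 in U0126 and 0 in the average, the interaction of the rapid list at 30 min was 0.0261, and the ERK feedback list at 30 min (-0.19) did not pass.

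Leaving out 1 library at a time, which leaves its group with 1 library assumed to vary like the others, gave 4 to 16, 9 to 578 and 3 to 24 calls for activity at 10, 30 and 60 min. U0126 effects ranged from 0 to 4 at 10 min (4 without vehicle 10 min replicate 2), 0 to 1 at 360 min and 0 to 3 in the average. Activity in U0126 ranged from 0 to 2, 4 to 258 and 4 to 10. All other counts of the fits without the block, H3K27ac included, stayed at 0, and no library was left out of the blocked H3K27ac fits. The rapid list ranged from -0.585 (without vehicle 30 min replicate 2) to 0.0227 (without replicate 1) for U0126 at 30 min and from -0.359 to -0.159 in the average, and its interaction from -0.46 to 0.0319 at 30 min and -0.236 to 0.14 at 60 min. The ERK feedback list ranged from -0.345 to -0.261 at 10 min, -0.373 to -0.17 at 30 min, -0.432 to -0.0707 at 60 min and -0.408 to -0.4 at 180 min, where U0126 had 1 library and the list did not pass without vehicle replicate 2. Its average stayed past the threshold, from -0.287 to -0.15. The H3K27ac regions of the delayed list ranged from -0.0292 (without vehicle 60 min replicate 2) to 0.168.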

Other observations

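The test between times was chosen only after the Egr1 value at 10 min was seen. The U0126 effect on Egr1 was larger at 10 min than at 60 min by -1.14 on the log2 scale (unadjusted p 0.00419), and this difference did not pass over the 43 genes tested (adjusted p 0.18).

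Windows of 1267 genes tested overlap the next window, so the signal there is shared. Among the 172 genes called at 30 min, 12 windows overlap the next called window. Overlaps of called genes with genes that were not called were not counted. The delayed list, which did not pass with U0126 in the average of 10, 30 and 60 min, had a median of -0.125, at percentile 0.18 of density-matched lists. The nearest gene of 10 H3K27ac regions differs between the 2 sheets; the distance to the gene named as nearest has a median of 45535.5 bp and reaches 4331544 bp.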
